A study of Mus musculus with 6 samples.

How the data were processed

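Gene expression was measured by RNA sequencing in prefrontal cortex homogenate of mice at postnatal week 8, in 6 libraries, 3 labelled wild type and 3 heterozygous for the 16p11.2 duplication. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the TruSeq stranded total RNA kit with Ribo-Zero. The authors used cutadapt, TopHat2 and HTSeq with the mouse build mm10, per the submitters' processing notes, which give no versions. The annotation and the strand setting of the counting are not given in the sources used here. The authors deposited raw counts per gene, whole numbers that are not normalized, in 1 table of 6 columns and in 1 table per library. The 45801 named values of each library's own table were equal to those of the joint table. No label says that the libraries came from separate litters or batches, nor that each is a separate animal, so p-values measure the spread between these samples.

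The gene names of the deposited table did not line up with its counts. The table has 45807 lines of counts and 45801 names, with 6 blanks at the end, and 25 names had been turned into date serial numbers, as a spreadsheet does. Where a name is missing in the middle of the column, all later names sit against the counts of another gene. The offset between names and counts was estimated for each line with a hidden Markov model of the counts given the annotation class of the name, and it rose from 0 to 6 in 6 steps. At 15986 names the offset was 0 and at 29815 names (65.1%) it was 1 or more. In each of 89 windows of 500 lines, the offset at which counts correlated best with the protein-coding class of the names equalled that of the model. The windows used the same name classes and counts as the model, so they are not an independent check. Names within 25 names of a step, and names with a posterior under 0.999, were not used, which left 45340 lines named and 467 unnamed. On breaks simulated in the first 15000 lines, 14694 of 14694 used names had the true offset. The model had been learned on these same lines, so this does not measure its accuracy on other lines. As deposited, the wild type libraries together held 5 counts of Gad1 and 25 of Slc17a7, both abundant in cortex, and after re-alignment 9931 and 42353. Npas4 had 1201 counts as deposited and 991 after re-alignment. Names as deposited are among the alternatives.

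Unnamed lines held 6.853% to 8.332% of the counts of a library and were left out of library sizes and tests. Total counts were 12988457 to 21872271 per library, of which 12027109 to 20049871 were used. Counting error is small beside the spread between libraries for all but the genes with few counts. PCR reads without molecular identifiers are not independent molecules, so counts cover counting error only. Positions and annotation classes were taken from a GENCODE annotation of the same build, in which 92.0% of used names were found. No per-sample column was left unused.

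Duplication and wild type libraries were compared with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter by group and the quasi-likelihood F-test, and Benjamini-Hochberg adjusted p under 0.05. This kept 15409 genes, and the square root of the common dispersion was 0.0951. Fold changes are log2 values of duplication over wild type with their standard error, CPM values use TMM-scaled library sizes, and log2 CPM uses a prior count of 2. On simulated counts for the same 15409 genes and libraries, edgeR recovered 66.7% of 99 genes changed 1.5-fold and 91.9% of 99 genes changed 2-fold, with 18 calls among unchanged genes. The simulated genes varied independently, without differences between libraries that genes share. These rates therefore need not hold for the real libraries, where 0 of 23 tested interval genes passed over all genes.

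Gene lists for the interval, its flanks, pathways, cell types and sex were fixed in advance. For each list, members past the threshold were counted over all genes and adjusted over the list alone, and 32 pathway and cell type lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01. None of the 15 lists that passed did so with an estimated correlation (smallest adjusted p = 0.703) or with the directional test of fry (smallest adjusted p = 0.357). On simulated data camera called a list of 40 lowered genes and did not call one of 40 unchanged genes. The simulated genes varied independently, so this does not test the preset correlation. In the data the estimated correlation was 0.46 for chromatin regulators and 0.80 for respiratory chain genes. The medians of the flanking, GABA, ERK/MAPK and cholesterol lists changed sign with upper-quartile factors or library size only. For glucocorticoid-responsive and interferon-stimulated genes the median, the mean and the test differed in sign. Intervals of medians over genes come from 10000 bootstrap resamples, and genes are not independent replicates.

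Genes named in the text were each tested interval gene, Npas4, the 10 higher and 10 lower genes outside the interval with the smallest p, up to 4 members with the smallest p of a list that passed or is discussed, the flanking genes that passed with the first tested gene on each side, and Xist and 4 Y-linked genes. Some genes that this rule names are not reported here. Symbols of predicted genes were only counted, and genes that did not pass are said not to have. The further immediate early genes that passed over their list, and those that passed with the added covariate, were named after their values were seen. So were Ccdc101, Nupr1 and Zfp553.

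Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size only, no filter or a stricter one (CPM above 1 in 3 libraries), the replicate number as a block, leaving out each library in turn, an estimated correlation and fry. Added after seeing the data were edgeR's bias-adjusted deviances, sex as a covariate, leaving out both libraries numbered 2 and names as deposited. Unadjusted p for chromosome 7 was added then too, as was the level of TEC and sense intronic transcripts as a covariate. That level is the median over these genes of centred log2 CPM in each library. Sex was coded as Xist absent or present, since the labels give none.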

Results

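RNA from prefrontal cortex homogenate of mice at postnatal week 8 was sequenced in 3 libraries labelled wild type and 3 labelled heterozygous for the 16p11.2 duplication, a copy number gain linked in people to autism and schizophrenia. The mouse carries it as a duplication of the matching segment of chromosome 7. The line was made on a mixed C57BL/6N and 129Sv background and then crossed to C57BL/6 for 10 generations. The libraries were stranded total RNA libraries depleted of ribosomal RNA. Total gene counts were 12988457, 14369271 and 13889329 in wild type replicates 1 to 3 and 21872271, 14891890 and 16038828 in duplication replicates 1 to 3. A count of 15409 genes entered the test. The gene names of the deposited table had slipped against its counts for 65.1% of names, and values are given after re-alignment.

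Genes of the duplicated segment were higher in the duplication cortex. Of 23 tested interval genes, 20 rose (edgeR quasi-likelihood test, adjusted over the list alone), and 0 passed when adjusted over all genes, where the smallest adjusted p of any gene was 0.128. DESeq2 called 17 of them over all genes. With edgeR the count over all genes was 18 without wild type replicate 2 and 20 without a filter on low counts. It was 4 with the replicate number as a block. With the level of TEC and sense intronic transcripts, described below, as a covariate, which left 3 residual degrees of freedom, 0 passed over the list alone and the median log2 value was 0.61. The median log2 fold change of the 23 genes was 0.75, a fold of 1.68 with a bootstrap 95% interval over genes of 1.61 to 1.75. Aldoa, the glycolytic aldolase, was the most abundant of them and rose from 1772 ± 182 to 3273 ± 608 CPM (counts scaled to library size; mean ± SD, n = 3 per group). Mapk3, which encodes the kinase ERK1, rose by a log2 fold change of 0.59 ± 0.12 (SE). Kctd13, an adaptor of the CUL3 ubiquitin ligase, rose 1.68-fold, Taok2, a kinase of neuronal dendrites, 1.64-fold, Doc2a, a calcium sensor of transmitter release, 1.75-fold, and Coro1a, an actin regulator of leukocytes and neurons, 1.85-fold. The interval list was fixed before the data were examined and lies on mm10 chromosome 7 from 126689468, the start of Slx1b, to 127137823, the end of Spn.

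The other genes that rose lay in a narrow range. Log2 fold changes were 0.97 for Tmem219, 0.92 for Ppp4c, 0.82 for Mvp, 0.81 for Cdipt, 0.77 for Asphd1, 0.77 for Ino80e, 0.75 for Bola2, 0.75 for Maz, 0.71 for Ypel3 and 0.69 for Slx1b. They were 0.55 for Hirip3, 0.50 for Pagr1a and 0.42 for Sez6l2, the last of which lost its call in several alternatives, among them leaving out wild type replicate 2 or 3, duplication replicate 2 or both libraries numbered 2, the stricter filter and sex in the model. Gdpd3, a lysophospholipase D, stood apart at 3.53 ± 0.50, with 14 counts in the 3 wild type libraries together and 208 in the 3 duplication libraries. The 3 genes that did not pass were Kif22 at 0.55 ± 0.27, Prrt2 at 0.48 ± 0.52 and Fam57b at -0.17 ± 0.33. Kif22 passed as higher without wild type replicate 3, and Fam57b as lower without wild type replicate 2. Kif22 and Prrt2 had 53 and 24 counts in the wild type libraries together, and their 95% intervals included both 0 and 0.585. Of the tested interval genes only Mapk3, Ypel3, Ppp4c, Taok2 and Maz overlap no other annotated gene. Fam57b overlaps Aldoa on the opposite strand, Ino80e overlaps Doc2a, Gdpd3 overlaps the predicted gene Gm9967 on the opposite strand by 7568 bases, and Mvp and Pagr1a overlap the predicted gene Pagr1b. The strand setting of the counting is not given in the sources used here, so values of overlapping genes, Gdpd3 included, are uncertain. Same-strand overlaps, which no strand setting separates, include those of Mvp and Pagr1a with Pagr1b. Prrt2 overlaps the predicted gene Gm42742 on the same strand by 3567 bases, so its few counts need not mean low expression. Tbx6, Zg16, Qprt and Spn had too few counts to be tested. A log2 value of 0.585, which 3 copies against 2 would give, lay within the 95% interval of 17 genes, below that of 5 and above that of 1.

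**Figure D1:**
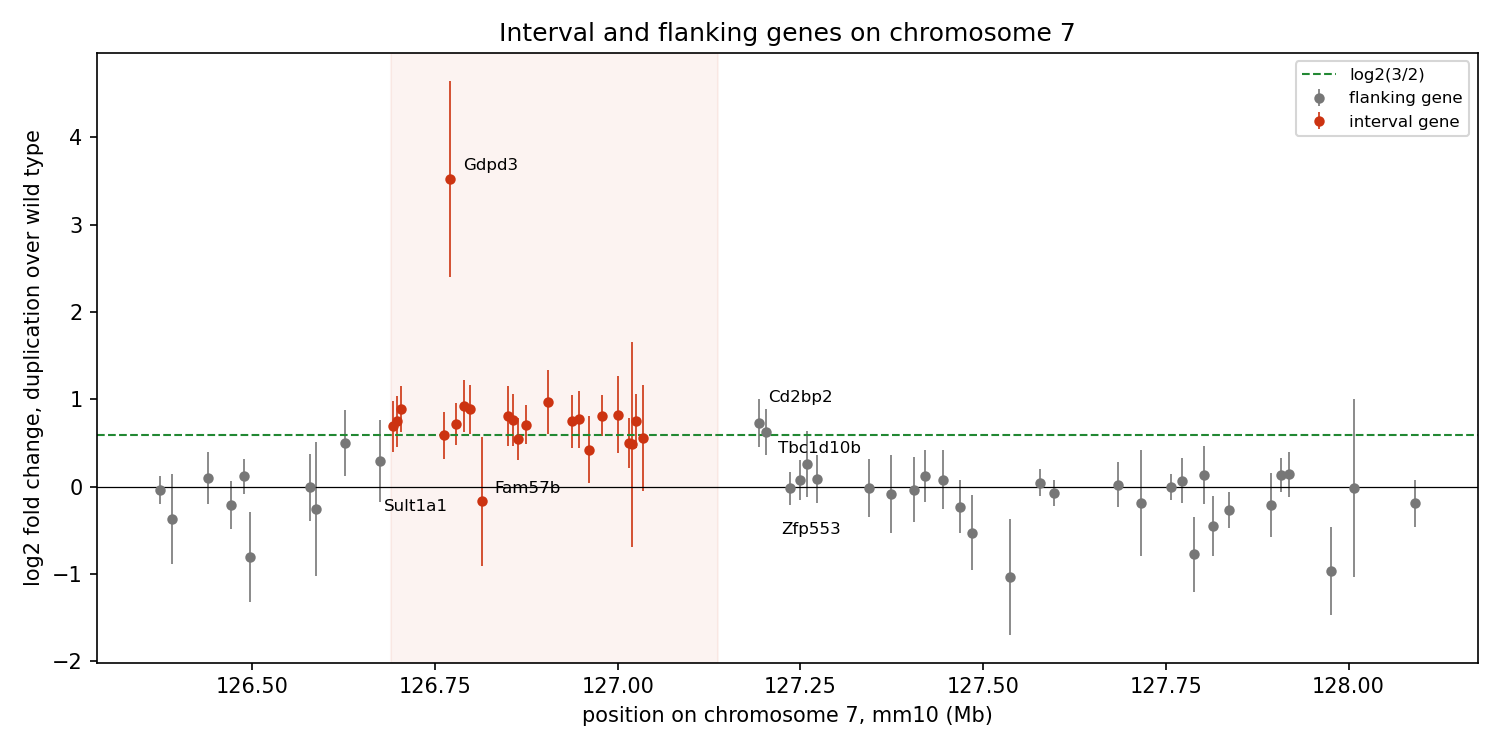
Log2 fold change of duplication over wild type (y axis) for tested interval genes (red) and flanking genes (grey) against gene midpoint on chromosome 7 of mm10 in Mb (x axis); bars are 95% intervals from edgeR, the shaded band is the fixed interval and the dashed line is log2(3/2), 0.585. Interval genes lie around a median of 0.75, Gdpd3 is at 3.53, and Cd2bp2 and Tbc1d10b lie above 0 to the right of the band while Zfp553 is at -0.02.

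The increase differed between the duplication libraries. The median of the 23 interval genes against the wild type mean was 1.51-fold in duplication replicate 1 (bootstrap 95% interval over genes 1.45 to 1.58) and 1.52-fold in replicate 3 (1.43 to 1.59). In replicate 2 it was 2.03-fold (1.83 to 2.13), and all 23 genes were higher there than the mean of the other 2 duplication libraries. The wild type libraries had median log2 ratios of 0.01, 0.05 and 0.0044. Without duplication replicate 2, the median log2 fold change of the interval genes was 0.58, against 0.75 with it. All 3 samples carry the same label, heterozygous, so the library is named here as labelled.

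**Figure D2:**
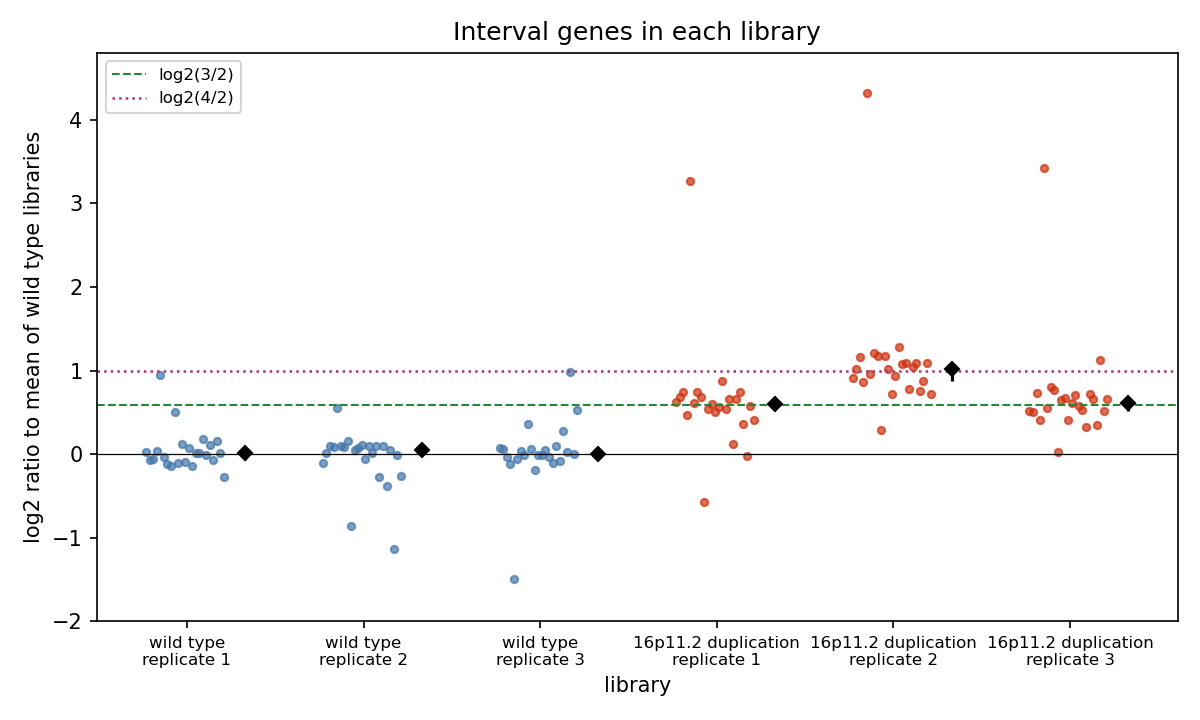
Log2 ratio of each of the 23 tested interval genes to the mean of the 3 wild type libraries (y axis) in each library (x axis); small points are genes, black diamonds are medians with bootstrap 95% intervals over genes, and lines mark log2(3/2) and log2(4/2). The medians are 1.51-fold, 2.03-fold and 1.52-fold in duplication replicates 1, 2 and 3.

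The increase ended between Tbc1d10b and Zfp553 on the high-coordinate side, and its low-coordinate edge was not placed. The tested gene nearest that edge, Sult1a1 (chromosome 7, 126672865 to 126676432), had a log2 fold change of 0.29 ± 0.21 and did not pass, with a 95% interval of -0.18 to 0.77 that includes 0.585. Nupr1, farther out (126623249 to 126630861), was at 0.50 ± 0.17 (0.12 to 0.88) and did not pass, and passed over the list alone without a filter on low counts, without wild type replicate 2 or without both libraries numbered 2. On the high-coordinate side, Cd2bp2, a spliceosome component (127191660 to 127196050), and Tbc1d10b, a Rab GTPase-activating protein (127197459 to 127208468), rose by 0.73 ± 0.12 and 0.62 ± 0.12. Zfp553, a zinc finger gene from 127233061, was at -0.02 ± 0.08. Ccdc101 has no position in the annotation used, and the order of names puts it between Nupr1 and Sult1a1. It was at 0.15 ± 0.13, with a 95% interval of -0.15 to 0.45 that leaves out 0.585. Against the other 2 duplication libraries, replicate 2 had log2 ratios of 0.425 for Cd2bp2, 0.451 for Tbc1d10b and -0.185 for Sult1a1. Of 41 flanking genes tested, 2 rose and 4 fell adjusted over the list alone, and 0 passed over all genes in edgeR and 5 in DESeq2. Without wild type replicate 2, edgeR called 14 over the list alone and 11 over all genes. The 4 that fell lay farther away and included Srcap, a chromatin remodeller, at -1.04 ± 0.29, Setd1a, a histone methyltransferase, at -0.78 ± 0.19, and Atxn2l at -0.81 ± 0.23. None of the 4 held without wild type replicate 1, without wild type replicate 3, without duplication replicate 1 or 2, or with sex or the TEC and sense intronic level in the model, while Cd2bp2 and Tbc1d10b were lost without wild type replicate 3 and with that level in the model. With that level, Srcap and Atxn2l turned to positive values that did not pass. Across chromosome 7 outside the interval, flanking genes included, 182 of 1040 genes (17.5%) had an unadjusted edgeR p under 0.05, against 18.9% of 13531 genes on other chromosomes (Fisher's exact test, two-sided, p = 0.284). With the adjusted edgeR threshold the count was 0 of 1040 and 0 of 13531. DESeq2 called 19 on chromosome 7 outside the interval, of 46 higher and 239 lower genes in all. Without wild type replicate 2 edgeR called 145 there, of 604 higher and 1767 lower genes in all. At unadjusted p under 0.05 the odds ratios of chromosome 7 in these fits were 0.94 and 0.89 (Fisher's exact test, p = 0.54 and 0.103).

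Over all 15409 tested genes, interval genes included, no gene passed in the edgeR quasi-likelihood test, with 0 higher and 0 lower, while 1086 higher and 1879 lower genes had an unadjusted p under 0.05, where chance gives 770. DESeq2 called 46 higher, 17 of them interval genes, and 239 lower, and limma-voom 0 and 0. The values of the 3 libraries per genotype did not overlap for 22.2% of genes, where chance gives 10%. Outside the interval the genes with the smallest p, none of which passed, included Trpc6, a calcium-permeable channel, at 0.47 ± 0.07, Myoc, myocilin, at 1.37 ± 0.21, Nbl1, a BMP antagonist, at 0.56 ± 0.09, Hpca, the neuronal calcium sensor hippocalcin, at 0.32 ± 0.06, and Met, the hepatocyte growth factor receptor, at 0.92 ± 0.16. Cd6, Lypla1 and Ogn were at 0.82 ± 0.15, 0.50 ± 0.09 and 1.92 ± 0.35. Aldoart1, a retrogene of Aldoa, was at 1.07 ± 0.19, and its value is uncertain because its reads can be shared with Aldoa.

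Lower in the duplication libraries, again without passing (edgeR, adjusted p of 0.162 for each), were Tenm2, a teneurin of synaptic adhesion, at -0.79 ± 0.14, Pcsk5, a proprotein convertase, at -0.69 ± 0.11, Col6a1, a collagen chain, at -0.55 ± 0.10, and Kcnq1ot1, the imprinted antisense RNA, at -0.87 ± 0.17. Catsper2, Adamts16 and Ttc28 were at -0.93 ± 0.16, -0.84 ± 0.15 and -0.56 ± 0.10, and Spaca6, Egfem1 and Plekha7 at -0.57 ± 0.11, -0.54 ± 0.10 and -0.51 ± 0.10. Transcripts of the annotation class TEC, unspliced EST clusters, had a median log2 fold change of -0.70 over 254 genes and sense intronic transcripts one of -0.75 over 38. With all libraries, edgeR called 188 genes higher and 917 lower without a filter on low counts, and 6 and 1 with the replicate number as a block. The count of calls also depended on wild type replicate 2: without it, 604 genes were higher and 1767 lower in edgeR with the filter and no block. That library lay at 4.05 on the first principal component (45.5% of variance), between wild type replicates 1 and 3 at -27.2 and -26.7 and the duplication libraries at 24.8, 17.8 and 7.23.

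Immediate early genes, which neurons transcribe within minutes of activity, were lower in the duplication cortex. The series title names one of them, Npas4, a transcription factor that regulates inhibitory synapses, and the comparison asks whether the list differs with genotype. Npas4 (chromosome 19, 4984355 to 4990316) was at 26.1 ± 5.0 CPM in wild type and 16.3 ± 2.5 CPM in duplication mice, a log2 fold change of -0.69 ± 0.16 and lower in each duplication library than in each wild type library. It fell when adjusted over the list alone (edgeR adjusted p = 0.0418) and did not pass over all genes (adjusted p = 0.173). It passed over all genes with DESeq2 (adjusted p = 0.00828). In edgeR it passed so without a filter on low counts (0.000827), without wild type replicate 2 (0.0295) and without both libraries numbered 2 (0.0256). Leaving out any other single library gave edgeR adjusted p of 0.259 to 0.493, the replicate block 0.109 and sex as a covariate 0.228. Over the list alone it lost its call without wild type replicate 1, duplication replicate 1 or duplication replicate 3. Of 37 measured list members, 9 fell, 1 rose and 27 did not pass, adjusted over the list alone. Fos, part of the AP-1 factor, fell by 0.74 on the log2 scale, the clock gene Per1 by 0.79, and Egr1, a zinc finger factor of plasticity, by 0.95. Egr4, Egr3, Sik1, Cyr61 and Jun made up the rest of those that fell, and Klf10 rose by 0.21.

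As a whole the list was lower than other genes (camera, preset correlation 0.01, adjusted p = 2.31e-05), with a median log2 fold change of -0.28 and adjusted p = 0.703 with an estimated correlation. Over all genes 8 members were called lower without wild type replicate 2, and 0 with all libraries. Over the list alone the count that fell was 12 without wild type replicate 2, 0 without wild type replicate 1, without duplication replicate 1 and without duplication replicate 3, and 2, Egr4 and Npas4, without duplication replicate 2. With the TEC and sense intronic level in the model it was 4, Npas4, Fos, Egr2 and Btg2, and the list again was lower (camera, adjusted p = 1.55e-08; 0.788 with an estimated correlation). In that model Per1 and Egr1 turned to positive values that did not pass. The list lay at 0.17, 0.15 and 0.03 in wild type replicates 1 to 3 and -0.28, -0.02 and -0.07 in duplication replicates 1 to 3. In the same order meningeal markers, described below, lay at -0.52, -0.58 and -0.18 and at 0.85, 0.27 and 0.05. A link between them was not tested.

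**Figure D3:**
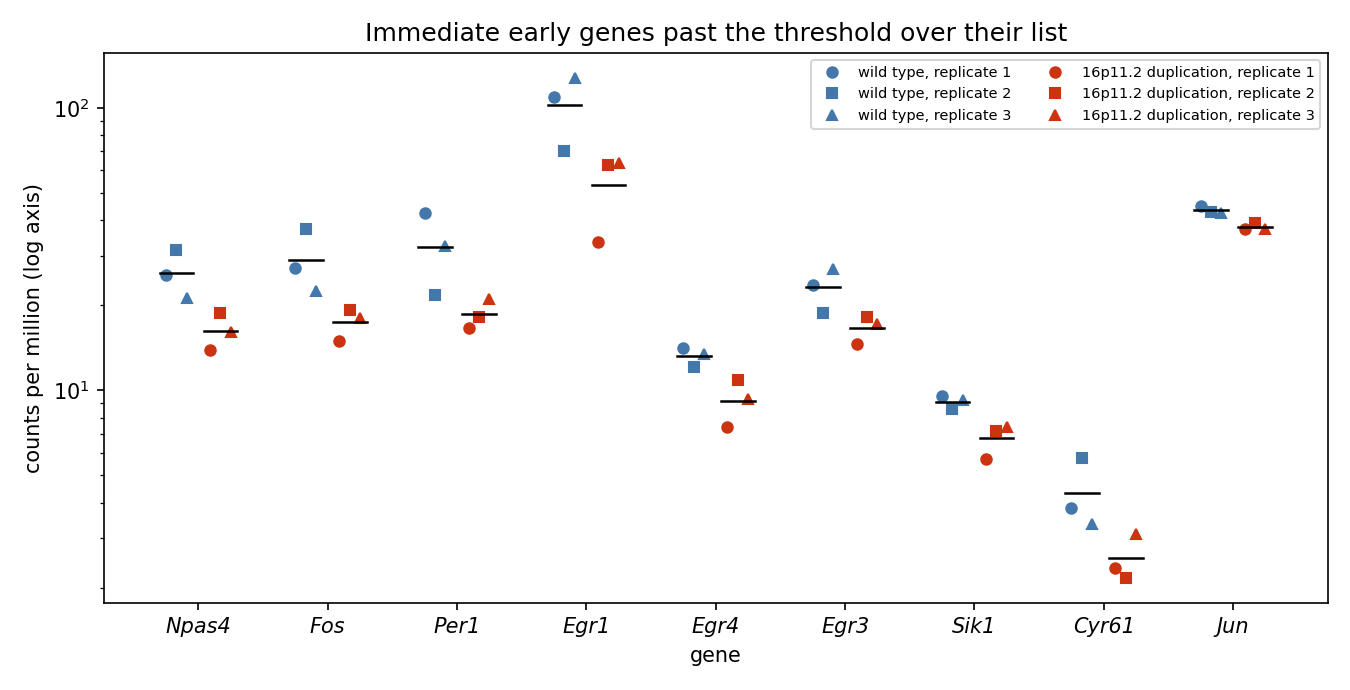
CPM (y axis, log scale) of the 9 immediate early genes that fell when adjusted over the list alone (x axis) in each library; symbols are replicates, colours are genotypes and black lines are means of 3 libraries. Npas4 is at 26.1 CPM on average in wild type and 16.3 CPM in duplication mice.

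No common shift was detected in genes of GABA signalling. Of 25 measured members 0 passed adjusted over the list alone, the median log2 fold change was -0.01, positive with upper-quartile factors or library size only, and the list did not pass (camera, adjusted p = 0.700). With the TEC and sense intronic level in the model the median was 0.10 and the list again did not pass (camera, adjusted p = 0.0528, and 0.788 with an estimated correlation). Nlgn2, an adhesion protein of inhibitory synapses, was at -0.85 ± 0.27, and the receptor subunit gene Gabra4 at 0.21 ± 0.07. Interneuron markers did not pass as a list either (adjusted p = 0.705), and 1 of 20 rose over the list alone, the peptide gene Cck at 0.34 ± 0.07, which is also made by pyramidal cells. Lhx6, Reln and Erbb4 were at -0.30 ± 0.12, -0.43 ± 0.17 and -0.26 ± 0.12.

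Chromatin regulators and several groups of neuronal genes were lower in the duplication libraries. Of 37 chromatin regulators linked to autism, 23 fell and 14 did not pass adjusted over the list alone, with a median log2 fold change of -0.29. Kmt2d, a histone H3 methyltransferase, fell by 1.43 on the log2 scale, the transcription factor Bcl11a by 0.60, Ankrd11 by 0.29 and the DNA methyltransferase Dnmt3a by 0.27. Of 45 voltage-gated ion channel genes 7 fell, among them the calcium channel genes Cacna1e by 0.74 and Cacna2d2 by 0.54 and the potassium channel gene Kcna1 by 0.39. Glutamate receptor genes (median -0.15, 0 of 24 past over the list alone) included Grik3 at -0.75 ± 0.21, Grm4 at -0.66 ± 0.20 and Grik5 at -0.57 ± 0.17. Among 35 synaptic vesicle genes (median -0.15) only the interval gene Doc2a passed, and Bsn and Syn1 were at -1.20 ± 0.35 and -1.02 ± 0.28. Of 32 postsynaptic density genes (median -0.10) 0 passed, with Nlgn3 at -0.57 ± 0.15.

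These lists passed camera with the preset correlation, at adjusted p of 2.20e-12 for chromatin regulators, 5.89e-07 for ion channels, 0.000626 for glutamate receptors, 0.00462 for synaptic vesicle and 0.0089 for postsynaptic density genes. With an estimated correlation none did (adjusted p = 0.703 to 0.705). Of the 10 ways to split the 6 libraries into 3 and 3, 4 gave 15 or more passing lists, the real split included. The synaptic vesicle list did not pass without wild type replicate 1 (adjusted p = 0.0831), nor the postsynaptic density list without wild type replicate 1 or duplication replicate 1 (highest adjusted p of 0.149). The level of TEC and sense intronic transcripts moved with them: it was 0.46, 0.01 and 0.51 on the log2 scale around the mean of the libraries in wild type replicates 1 to 3, and -0.43, -0.41 and -0.12 in duplication replicates 1 to 3. In the same order, chromatin regulators lay at 0.22, -0.05 and 0.26 and at -0.24, -0.13 and -0.08. With that level as a covariate in edgeR the direction of these 5 lists turned, and the level itself correlated with genotype at -0.863. Camera then placed them higher in duplication libraries, at adjusted p of 0.028 for chromatin regulators (median 0.09), 2.63e-05 for ion channels (median 0.15), 0.00132 for glutamate receptors and 0.000106 for synaptic vesicle genes, and 0.052, which did not pass, for postsynaptic density genes. With an estimated correlation each had an adjusted p of 0.788 in that model. The lower level of these lists in duplication libraries therefore depended on the model.

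Genes of the respiratory chain and of ribosomes lay on the other side. All 56 nuclear-encoded respiratory chain genes had a positive log2 fold change, with a median of 0.15 (camera, adjusted p = 1.29e-10), and 0 passed adjusted over the list alone. Uqcrfs1 and Ndufs7, subunits of complexes III and I, were at 0.31 ± 0.08 and 0.24 ± 0.07. Of 53 cytosolic ribosomal protein genes 48 were higher, with a median of 0.11 (adjusted p = 4.53e-05), and Fau was at 0.21 ± 0.06. Heat shock genes (median 0.12, adjusted p = 0.0374) and histone genes (median 0.08, adjusted p = 0.0485) also passed, with 0 members past over the list alone. Heat shock genes did not pass without wild type replicate 1 or duplication replicate 2 or 3 (highest adjusted p of 0.791), nor histone genes without wild type replicate 1 or duplication replicate 2 (0.252). With an estimated correlation the 4 lists had adjusted p of 0.703, 0.713, 0.761 and 0.703. With the TEC and sense intronic level in the model the first 2 lists turned lower, respiratory chain genes at a median of -0.07 (camera, adjusted p = 0.00819; 0.857 estimated) and ribosomal protein genes at -0.09 (4.84e-05; 0.788 estimated), and heat shock and histone genes did not pass (0.0715 and 0.968). Respiratory chain genes in wild type replicate 2 lay at 0.07, beside -0.20 and -0.13 in wild type replicates 1 and 3 and 0.11, 0.06 and 0.06 in the duplication libraries.

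**Figure D4:**
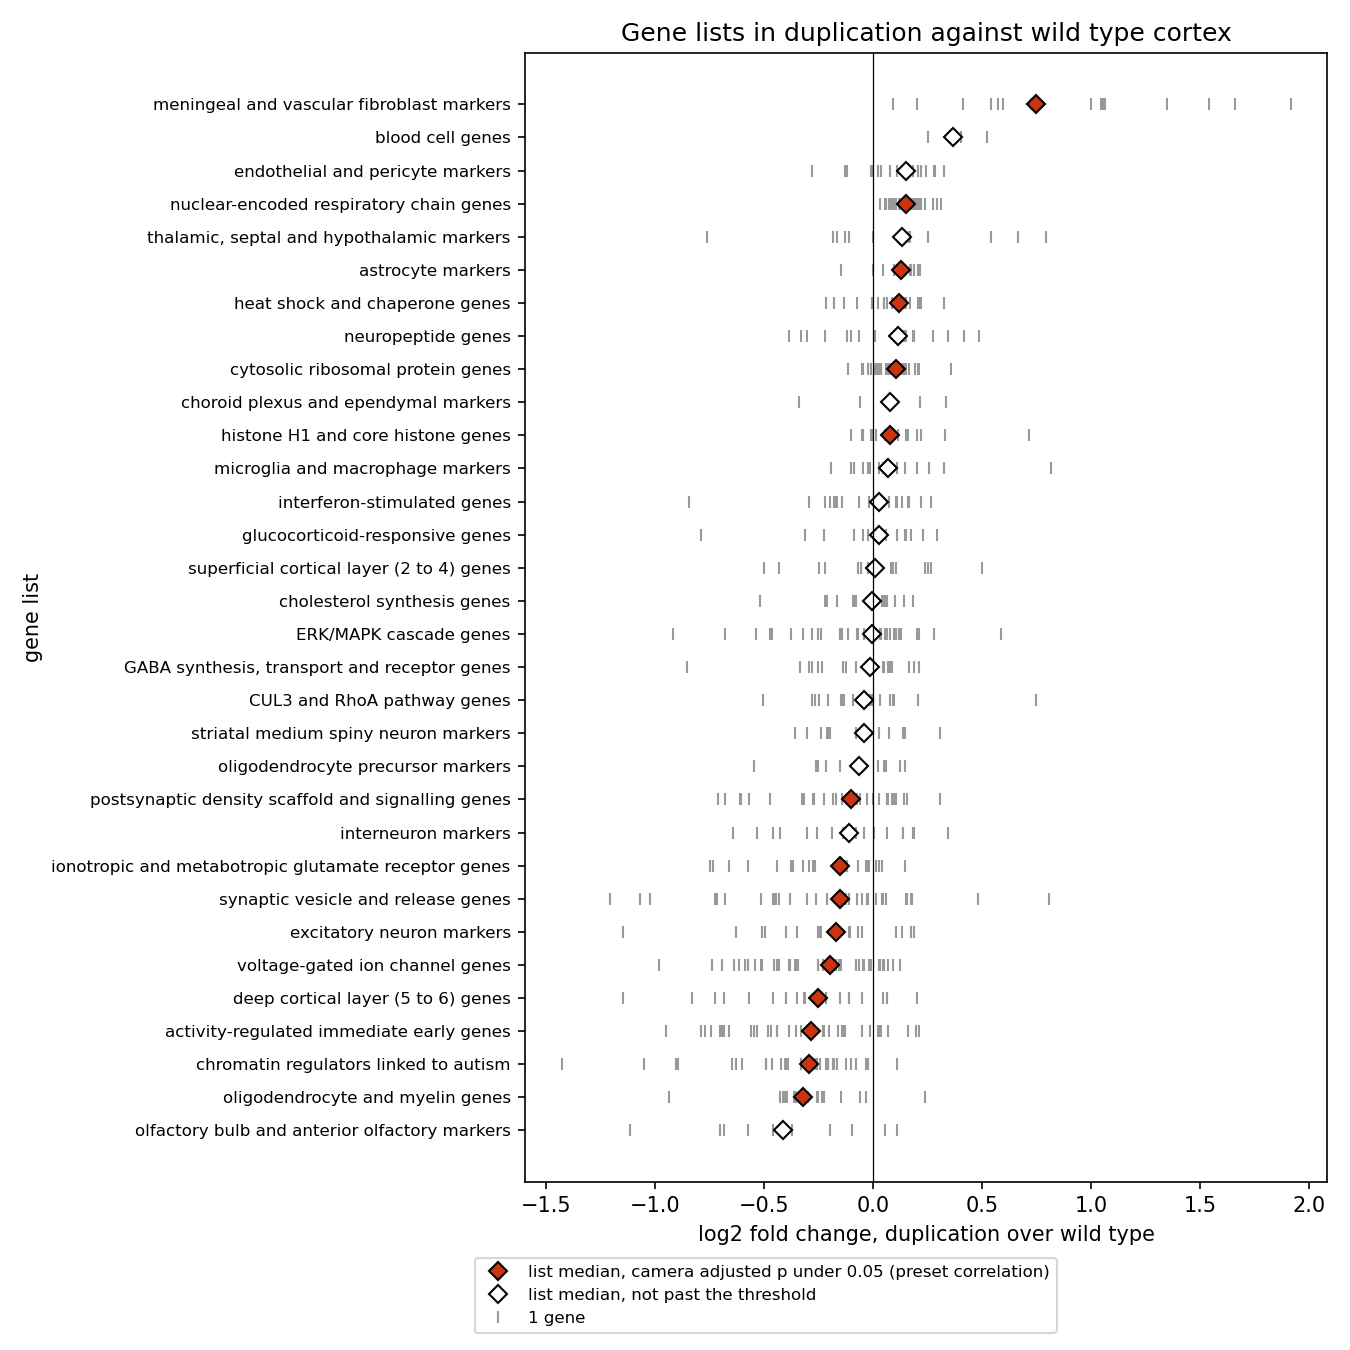
Log2 fold change of duplication over wild type (x axis) for the tested members (grey ticks) and the median (diamonds) of 32 gene lists (y axis); red diamonds mark 15 lists with a camera adjusted p under 0.05 at the preset correlation. Meningeal markers have the highest median, 0.75, and chromatin regulators lie at -0.29.

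Cell type markers showed their widest difference in fibroblasts of the meninges and vessel walls. All 17 measured markers were higher in duplication mice, 8 rose and 9 did not pass adjusted over the list alone, and the median log2 fold change was 0.75 (camera, adjusted p = 1.32e-12; adjusted p = 0.703 with an estimated correlation). With the TEC and sense intronic level in the model the list stayed higher, at a median of 0.54 (adjusted p = 2.83e-06; 0.788 estimated). Ptgds, prostaglandin D synthase of the meninges, rose from 85.2 ± 19.7 to 217 ± 95.5 CPM, and the matrix genes Ogn and Mgp rose by 1.92 ± 0.35 and 1.06 ± 0.22. The transporter gene Slc22a6 rose by 1.54 ± 0.35. The level was 0.85 in duplication replicate 1 and 0.05 in replicate 3 around the mean of the libraries. Members varied together around the mean of each genotype, with a mean pairwise correlation across genes of 0.70, where the 95th percentile of 10000 random lists was 0.09. Such a correlation was not particular to these markers. The correlation that camera estimated was 0.77 for them, 0.80 for respiratory chain and 0.73 for myelin genes.

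Astrocyte markers were higher by a median of 0.13 (adjusted p = 0.00171), with S100b at 0.21 ± 0.07. Oligodendrocyte and myelin genes were lower by a median log2 value of -0.32 (adjusted p = 0.00376), with Myrf at -0.93 ± 0.28, Mag at -0.40 ± 0.18 and, on the other side, Enpp2 at 0.24 ± 0.08, and the list did not pass without wild type replicate 3 or duplication replicate 2, with a highest adjusted p of 0.323. Deep cortical layer genes (median -0.25, adjusted p = 0.00376) included Ntsr1 at -0.73 ± 0.28, and did not pass without wild type replicate 3 (adjusted p = 0.137). Excitatory neuron markers (median -0.17, adjusted p = 0.0356) included Tbr1 at -0.63 ± 0.20, and did not pass without wild type replicate 3 or duplication replicate 1 (highest adjusted p of 0.124). No member of these 4 lists passed over its list alone, and with an estimated correlation their adjusted p were 0.703, 0.709, 0.703 and 0.703. None of the 4 passed with the TEC and sense intronic level in the model (camera, smallest adjusted p = 0.228).

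Other lists did not pass. Microglia and macrophage markers had an adjusted p of 0.0587, with the perivascular macrophage gene Mrc1 rising by 0.82 ± 0.20 over its list alone. Endothelial and pericyte markers were at 0.0531, with Vtn at 0.28 ± 0.09 and Cldn5 at 0.21 ± 0.09, and blood cell genes at 0.0589. These 3 lists passed in 2, 4 and 3 of the 6 fits that left out 1 library, and olfactory markers and the ERK/MAPK cascade in 2 and 1. With the TEC and sense intronic level in the model blood cell, interferon-stimulated and ERK/MAPK genes passed (camera, adjusted p of 0.000771, 4.26e-05 and 0.028; 0.788 estimated), the first 2 as lower and the last as higher. Adjusted p were 0.329 for oligodendrocyte precursors, 0.758 for choroid plexus and ependyma, 0.705 for striatal neurons, 0.151 for olfactory markers, 0.151 for thalamic, septal and hypothalamic markers and 0.726 for superficial cortical layers. Among pathways they were 0.151 for neuropeptides, 0.528 for the ERK/MAPK cascade, 0.489 for CUL3 and RhoA, 0.799 for glucocorticoid-responsive, 0.962 for interferon-stimulated and 0.936 for cholesterol synthesis genes. Within the ERK/MAPK list only the interval gene Mapk3 passed over the list alone. Within the CUL3 and RhoA list the interval gene Kctd13 rose, and Rock1 and Ssh2 fell by 0.28 and 0.50.

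**Figure D5:**
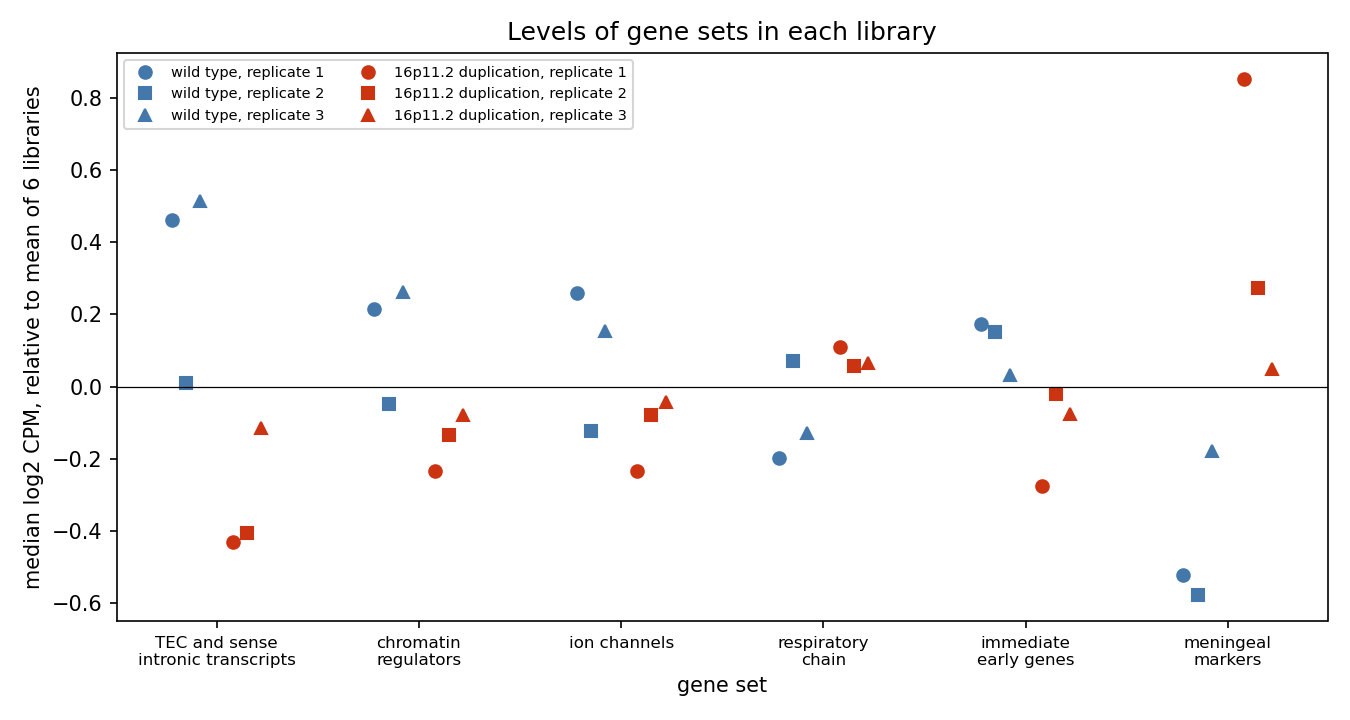
Median log2 CPM of 6 gene sets (x axis) in each library relative to the mean of the 6 libraries (y axis); symbols are replicates and colours are genotypes. Wild type replicate 2 lies at 0.01 for TEC and sense intronic transcripts and at 0.15 for immediate early genes, and duplication replicate 1 at 0.85 for meningeal markers.

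The labels give no sex, and the sex-linked genes differed between libraries in the same way in both genotypes. Xist, transcribed from the inactive X chromosome, had 0 counts in wild type replicate 1 and duplication replicate 1, which allows at most 3 counts, and 2130, 3531, 2090 and 2567 counts in wild type replicates 2 and 3 and duplication replicates 2 and 3. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 2515 and 4617 counts in the libraries numbered 1 and 4 and 10 counts in those numbered 3. The sex covariate was coded as Xist absent or present, which put the libraries numbered 2 with those numbered 3. With it the edgeR test again called 0 higher and 0 lower genes over all genes, and 19 interval genes over the list alone.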

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

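Tests chosen only after the result was seen were those of library differences, of sex, of scaling and copies in duplication library 2, and the bounds of the scaling and sex tests of that library. The tests of depth, genomic DNA and the model with the level of unspliced-type transcripts were written before their results, and the directions of the gene lists in that model were looked at afterwards.

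Counts in lines with no usable name, which enter no comparison, made up 8.332% of the counts in 1 library and 6.853% in another, the highest and lowest of the 6. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together, which females lack, had 177 reads in wild type library 2 and 182 in duplication library 2, which also held 2130 and 2090 reads of Xist, so both kinds of sex-linked reads were present in each. Per used count of the library, the Y-linked genes stood at 3.91% to 7.58% of their level in the library numbered 1 of the same genotype, gene by gene, and the source of the reads was not tested.

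Interval genes were higher in duplication library 2 than in the other 2 duplication libraries, by a median log2 ratio of 0.428 (bootstrap 95% interval over genes 0.373 to 0.495). A scaling error of that library would raise flanking genes by as much, and all 41 lay at a median of -0.0218 (-0.144 to 0.0375), although Cd2bp2 and Tbc1d10b, which rose with the interval, lay at 0.438. An effect of sex or of the number 2 would appear in wild type library 2, where interval genes lay at 0.0774 above the other 2 wild type libraries (-0.0249 to 0.144). Both intervals lie below 0.2, a bound set after the values were seen; an earlier bound, within 0.1 of 0 with the whole interval, was not met by either. A candidate explanation is 4 copies of the segment in that library, for which log2(4/3), 0.415, lies within the interval; this is a hypothesis from a single library, and the label of heterozygosity goes against it.

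Transcripts of the unspliced kind, TEC and sense intronic, were lower in duplication libraries. Thinning each library to the smallest total left their median at -0.669 (-0.779 to -0.618). Thinning keeps each gene's expected share of its library, so it could hardly move a scaled fold change and cannot decide on depth. Receptor genes silent in cortex carried 0.00317 of the excess of reads per kilobase that TEC genes had in wild type, which argues against genomic DNA. Library differences unrelated to genotype may be the source and cannot be told apart from genotype: the widest range within a genotype was 0.778 of the difference between genotypes, with wild type library 2 at 0.01 beside 0.46 and 0.51. With this level in the model chromatin and ion channel genes turned higher (camera, adjusted p of 0.028 and 2.63e-05, 0.788 with an estimated correlation), and respiratory chain and ribosomal protein genes lower (0.00819 and 4.84e-05, 0.857 and 0.788 estimated), so the directions of these lists may rest on it. A genotype effect on such transcripts stays open and untested.

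Immediate early genes were lower in duplication libraries. Each genotype had 1 library without Xist and 2 with it, a difference of 0, which argues against sex of the animals. With the level of unspliced-type transcripts in the model their median log2 fold change was -0.229 (-0.452 to -0.0739), which leaves open whether the same library differences may contribute. Interval genes went from 20 to 0 calls over their list in this model, at a median of 0.608 (0.574 to 0.708) against 0.748 (0.688 to 0.809); it left 3 residual degrees of freedom, its level correlated with genotype at -0.863, whether the first or the second ended the calls was not tested, and Npas4 was at -1.10 ± 0.25 (SE). A difference in neuronal activity between genotypes stays open and was not tested, since the labels do not say how mice were handled.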

How the results depend on the processing

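Alternatives chosen after the result was seen were sex as a covariate, leaving out both libraries numbered 2, names as deposited, edgeR's bias-adjusted deviances, unadjusted p on chromosome 7 and the level of unspliced-type transcripts as a covariate. With limma-voom, RLE, upper-quartile or library-size factors, the stricter filter and bias-adjusted deviances, edgeR or limma called 0 genes higher and 0 lower, and 19 or 20 interval genes over the list alone. The share of higher genes among those with p under 0.05 was 36.6%, and 47.4% with upper-quartile factors. Over all genes, DESeq2 called 46 genes higher and 239 lower. These held 17 interval, 5 flanking, 19 chromosome 7 (outside the interval, flanking genes included) and 3 immediate early genes. Without a filter these were 188, 917, 20, 7, 70 and 10, with 10 flanking and 17 immediate early genes over the list alone. Without both libraries numbered 2 they were 170, 1138, 16, 9, 87 and 7, with 11 flanking genes over the list alone. At unadjusted p under 0.05 they were 1086 and 1879 genes and 182 on chromosome 7. Correlations between samples of 1 replicate number were 0.101, 0.0624 and 0.311, and wild type 2 correlated best with duplication 1, at 0.158. Sex-linked reads followed the number in both genotypes, so whether the numbers mark pairs was not settled. With the replicate block edgeR called 6 genes higher and 1 lower, 4 interval genes and 1 flanking gene. On chromosome 7 outside the interval, flanking genes included, it called 1. With sex as a covariate 2 flanking genes passed over the list alone. With names as deposited 15 interval, 2 flanking and 0 immediate early genes passed over their lists, and 7 gene lists, since the names then belong to other genes; the name Npas4 then stood at 0.23 against -0.69 after re-alignment. With the level of unspliced-type transcripts in the model 0 interval, 0 flanking and 4 immediate early genes passed over their lists, and 11 gene lists. With an estimated correlation 0 lists passed, and 0 with fry.

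Leaving out 1 library gave 0 to 604 genes higher and 0 to 1767 lower, 0 to 18 interval, 0 to 11 flanking, 0 to 145 chromosome 7 (outside the interval, flanking genes included) and 0 to 8 immediate early genes over all genes, with the highest of each without wild type replicate 2. Over the list alone it gave 19 to 20 interval, 0 to 14 flanking and 0 to 12 immediate early genes, and 11 to 19 lists passed. The median log2 fold change of interval genes was 0.58 to 0.83. Over alternatives other than names as deposited, 153 values of named genes lost and 198 gained a call, 1860 stayed, and 28 moved, among them Prrt2 at -0.05 without both libraries numbered 2. The 11 that reversed all did so with the level of unspliced-type transcripts in the model, where none passed: Per1 at 0.14, Egr1 at 0.11, Cacna2d2 at 0.0016, Kcna1 at 0.0308, Cacna1e at 0.18, Bcl11a at 0.14, Kmt2d at 0.59, Atxn2l at 0.22, Srcap at 0.49, and others at 0.17 and 0.16. The cause of these moves was not tested.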

Other observations

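Tests of other splits of the libraries were chosen after the results were seen. Lists of markers of other tissue did not pass with all libraries, and none of their members named here passed over its list alone. The olfactory list passed without wild type replicate 3 and without duplication replicate 2. It also passed without both libraries numbered 2 (camera, adjusted p = 0.0231). Thalamic, septal and hypothalamic markers included Lhx2 at 0.25 ± 0.08, Lef1 at 0.66 ± 0.23 and Zic4 at 0.79 ± 0.34 (SE, edgeR). Olfactory markers had a median of -0.41 (camera, adjusted p = 0.151; 0.761 with an estimated correlation), with Cdhr1 at -1.11 ± 0.60 and Cdca7 at -0.68 ± 0.21. Among neuropeptide genes Tac2 was at 0.49 ± 0.14 and Crhbp at 0.28 ± 0.10, neither past the threshold. Siglech, a microglial receptor, was at 0.33 ± 0.09 and did not pass. These genes were named after their values were seen.

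The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For genes higher and for genes lower over all genes, all 10 splits gave as many as the real 0. So they did for interval, flanking, immediate early and chromosome 7 genes outside the interval over all genes (10 each, highest other 0). For interval genes over the list alone 1 split, the real one, gave 20 and the highest other 0, and for immediate early genes 1 split gave 9 and the highest other 0. For flanking genes 1 split gave 6 and the highest other 3. The median log2 fold change of interval genes was 0.75, and the highest other 0.40 (1 split as large). For gene lists 4 splits gave 15 or more, with a highest other of 17 for wild type 1 and 3 with duplication 2 against the rest.

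By how their counts differ beyond sampling noise, wild type library 2 lay nearer to the 3 duplication libraries, at a chi-square per gene of 3.89 to 6.79, than to wild type libraries 1 and 3, at 15.3 and 12.2. Of 4 classes of protein-coding genes by gene length, the shortest had a median log2 fold change of 0.07 and the longest one of -0.08.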
